A study of Homo sapiens with 22 samples.

How the data were processed

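RNA bound by PSF (also called SFPQ, a nuclear RNA-binding and splicing protein) was measured in human prostate cancer cell lines by RNA immunoprecipitation sequencing (RIP-seq) and by crosslinking immunoprecipitation sequencing (CLIP-seq). The series holds 22 samples. The RIP-seq part analysed here holds 12 libraries: an input library and a PSF-RIP library from each of 3 lines (LNCaP, 22Rv1 and a line labelled LTAD) after vehicle (ethanol) or 10 nM dihydrotestosterone (DHT) for 24 h. Each line, treatment and assay has 1 library, so the 6 line-treatment pairs of input and PSF-RIP are the samples of the PSF-RIP comparison, and the 3 lines are the samples of the DHT comparison. In the comparisons of lines, the vehicle and DHT libraries of a line are its 2 samples. No label says that these came from separate cultures. The p-values measure the spread between these libraries that is left after a DHT term shared by the lines. That spread holds responses to DHT that differ between lines, and the rest of it may be technical. Cells were kept for 3 days in medium with 2.5% charcoal/dextran-treated serum before the hormone, per the labels. LTAD cells were cultured with 10% charcoal/dextran-treated serum without phenol red, per the labels, which do not spell out the name. The RIP was made with a Millipore EZ-Magna kit and the libraries with Agilent's strand-specific SureSelect kit, per the labels. No immunoglobulin control library was analysed here, so enrichment is always relative to the input of the same line and treatment.

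Each RIP or input file holds whole-number counts of uniquely mapped reads per RefSeq transcript, intron, antisense strand and intergenic interval of hg19, not normalized by the authors, per the file headers. The submitters' processing notes name GRCh37, TopHat2 2.1.0, Bowtie2 2.2.6 and Bowtie without saying what each did. Reads on the sense strand of exons were used for the comparisons. The files list 48606 transcripts of 20294 gene symbols, and 10284 genes have more than 1 transcript row. Each gene was represented by the transcript with the highest mean count over the libraries. Of symbols on 1 strand whose start, end and length lay within 5 bp of each other, 1 was kept. The 34 mitochondrial symbols are named without coordinates, because versions of the hg19 reference differ in their mitochondrial sequence. The 4 CLIP files are peak lists in LNCaP cells, called per library (2 per treatment), and hold a position and a score per peak as deposited by the authors. The caller's settings are not given in the sources used here, and the score is used only to rank peaks within a list. All 4 lists start at a score of 50 within rounding, so they had been filtered on it. The 2 CLIP input libraries were not analysed here.

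A second LNCaP set of 4 samples in 2 tables was left out: its labels contradict each other and its tables repeat column names, so 12 columns of read counts, RPM and RPKM could not be matched to a sample and were not used here. The planned description of that set was therefore not made.

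Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by its quasi-likelihood test, with TMM scaling, edgeR's default expression filter and Benjamini-Hochberg adjustment at 0.05 over the genes of each of 7 comparisons. Every adjusted p for a gene comes from this test unless another is named. PSF-RIP was compared with input in a model with additive terms for line and treatment. The other comparisons used 1 model over all 12 libraries with line by assay and treatment by assay terms. Values are log2 fold changes with their standard error (SE) and the number of pairs or lines with that direction. Per-pair values use a prior count of 2. Where a group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group, and where it had 1 to 3 reads the ratio of summed reads is given with an exact 95% interval. Both use TMM-scaled library sizes. Intervals and floors cover counting error only, and a bound against the floor leaves out the error of the other group's count.

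The 21 gene lists, the comparisons, the tests and the rule for named genes were set before the data were examined. SFPQ, NONO, PSPC1, KLK3, NEAT1 and MALAT1 are given in every comparison. The rule further names the 12 highest and 12 lowest genes for PSF-RIP against input and the 10 highest and 10 lowest for each other comparison, among genes past the threshold, at or above the median expression and with the same sign in each pair, line or treatment. For CLIP it names the 10 highest-scoring peaks shared by both lists of a treatment, and for a gene list the members with the smallest p. The lists are androgen-induced, androgen-repressed, spliceosome core, SR protein, hnRNP, paraspeckle, nuclear and prostate long noncoding RNA, snoRNA host, structured RNA, ribosomal protein, oxidative phosphorylation, histone, cell cycle, p53 target, androgen and cholesterol synthesis, unfolded protein response, long neuronal-type, luminal, basal, neuroendocrine, and stromal and leukocyte genes. List members called were counted over all genes and adjusted over the list alone. Lists were also tested with camera at a preset correlation of 0.01, repeated with an estimated correlation, and with fry, each adjusted over the lists.

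Input and PSF-RIP libraries share a line and treatment by the labels. Their deviations from the group means correlated across 13776 genes at 0.939 and 0.934 in 22Rv1, 0.844 and 0.817 in LNCaP, and 0.791 and 0.844 in LTAD (vehicle and DHT). These means pool lines, so the values carry line differences and do not by themselves show pairing within a line. For example, 22Rv1 vehicle input correlated at 0.929 with its own PSF-RIP library and at 0.915 with that of DHT. The pairs, as labelled, were also used as a replicate block. CLIP peaks were compared by an overlap of at least 1 bp with bedtools 2.31.1, against 100 shuffles of the peaks within genes, and placed on GENCODE 44 lifted to GRCh37. Fisher's exact test (two-sided, scipy 1.17.1) compared genes with and without a peak in both lists of a treatment, overlapping or not, with Mantel-Haenszel odds ratios over 10 deciles of gene span and of expression (statsmodels 0.14.6). Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

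The tests were tested on simulated data, with 200 genes changed by known folds in counts drawn from the means of the real libraries. All other genes were set to no change. The real PSF-RIP comparison called 7752 of 13367 genes, so the simulated shares may not carry over to it. For PSF-RIP against input (13071 genes), 64.2%, 92.5% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold were called (43, 62 and 63 genes), with 15 false calls. For the difference in enrichment between 22Rv1 and LNCaP (13617 genes) the shares were 1.5%, 13.4% and 59.1% (1, 9 and 39 genes), with 5 false calls. For DHT in input (13577 genes) they were 9%, 52.2% and 80.3% (6, 35 and 53 genes), with 9 false calls. For 22Rv1 against LNCaP input (12767 genes) they were 7.5%, 46.3% and 81.8% (5, 31 and 54 genes), with 5 false calls. False calls are to be read against the genes called, not against all genes fitted. The fit with the replicate block, the comparisons of LTAD with LNCaP and that of DHT in enrichment were not simulated.

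Alternatives set beforehand were median-ratio scaling, no expression filter, summed isoforms, DESeq2 1.42.0, the replicate block, leaving out each line, single treatments, subsets of libraries, other overlap rules and other gene rules for CLIP. Alternatives chosen after seeing the data left out mitochondrial genes, RPPH1 and RMRP, thinned every library to the shallowest, or removed the trend of counts with exonic length in each library. The value of 1 Y-linked gene among the named genes is not given, and 2 other genes that the rule names are not reported here.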

Results

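RNA recovered with PSF (SFPQ), a nuclear protein of splicing and of paraspeckles, was compared with input RNA in 3 prostate cancer lines. LNCaP is an androgen-responsive line, 22Rv1 is derived from a relapsed xenograft, and the line labelled LTAD was grown in steroid-depleted serum. Cells received vehicle or the androgen DHT (10 nM, 24 h). There was 1 input and 1 PSF-RIP library per line and treatment, 12 in all. Input libraries held 1073228 (LTAD vehicle) to 3014049 (22Rv1 vehicle) mapped reads and PSF-RIP libraries held 4641602 (LNCaP DHT) to 10439461 (22Rv1 vehicle). In LNCaP, 4 lists of PSF-CLIP peaks were also examined, 2 per treatment. Coordinates are on hg19.

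The classes of reads differed between input and PSF-RIP in each line and treatment. Mitochondrial genes took 10.3% (LTAD DHT) to 21.8% (22Rv1 vehicle) of mapped reads in the inputs and 0.259% (LTAD DHT) to 0.872% (22Rv1 vehicle) in PSF-RIP. Intergenic reads made up 10.7% to 13.9% of the inputs and 5.84% to 6.79% of PSF-RIP. Of intronic and nuclear exonic reads together, the intronic share was higher in PSF-RIP than in input in 6 of 6 pairs, from 19.5% to 22.6% in 22Rv1 vehicle and from 12.3% to 12.5% in LTAD DHT at the ends of the range. The intronic share was also lower after DHT than after vehicle in 6 of 6 line and assay combinations. No test was run on these shares.

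**Figure D1:**
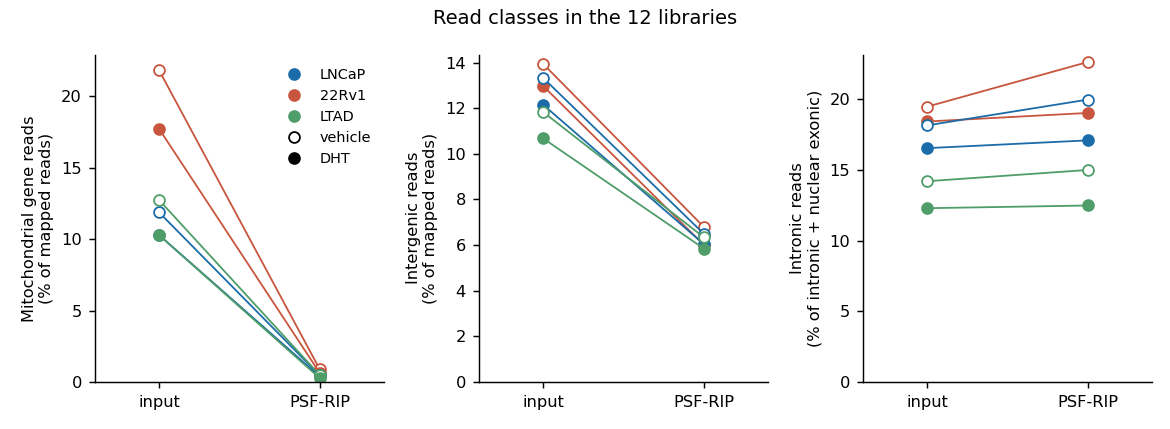
Percent of mapped reads in mitochondrial genes (left), percent of mapped reads between genes (middle) and intronic reads as a percent of intronic and nuclear exonic reads (right), for input and PSF-RIP; each point is 1 library, colours are lines, open points vehicle, filled points DHT, and lines join a pair. Mitochondrial reads fell from at least 10.3% in each input to at most 0.872% in each PSF-RIP library.

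The first comparison asked which RNAs were recovered with PSF relative to input in the 3 lines. RSRP1 (1:25568728-25664745), which encodes an arginine- and serine-rich protein, had the highest recovery, log2 2.08 ± 0.14 (SE, higher in 6 of 6 pairs, adjusted p = 9.45e-11 by edgeR's quasi-likelihood test). CCNL2 (1:1321091-1334718), a cyclin of pre-mRNA processing, was at 1.64 ± 0.11 (6 of 6, adjusted p = 4.77e-11). The nuclear long noncoding RNA MALAT1 (11:65265233-65273983) rose by 1.24 ± 0.16 (6 of 6, adjusted p = 1.65e-06) and SFPQ mRNA itself (1:35649201-35658743) by 0.99 ± 0.08 (6 of 6, adjusted p = 2.06e-09). At the other end, RPPH1 (14:20811230-20811570), the RNA of ribonuclease P, was at -7.43 ± 0.16 (0 of 6, adjusted p = 6.5e-19) and the mitochondrial mRNA MT-ND4 at -6.84 ± 0.14 (0 of 6, adjusted p = 6.5e-19).

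The other genes at the top were ZNF767P (1.71), COL27A1 (1.66), TUBGCP6 of the gamma-tubulin ring complex (1.65), CEP152 of the centrosome (1.62), GIGYF1 (1.61), TTC14 (1.61), MAPK8IP3 (1.60) and PKD1 (1.58), with SE of 0.10 to 0.18. PKD1 has near-identical pseudogene copies, and the readthrough transcripts CHKB-CPT1B (1.58) and STAG3L5P-PVRIG2P-PILRB (1.54) overlap other genes, so these 3 values are uncertain. Some input counts at the top were low (vehicle and DHT): COL27A1 had 4 and 1 reads in LNCaP, ZNF767P 9 and 5 in LTAD and RSRP1 7 and 7 in LTAD. The ratios of those pairs are imprecise. At the bottom stood MT-ND4L (-6.81), MT-ATP6 (-6.74), MT-ATP8 (-6.27), MT-CO2 (-6.14), MT-ND2 (-6.07), MT-TT (-5.95), MT-ND3 (-5.95), MT-RNR2 (-5.86), MT-CYB (-5.52) and MT-ND5 (-5.12), all of the mitochondrial genome and lower in 6 of 6 pairs. NEAT1, the architectural RNA of paraspeckles, was lower in PSF-RIP (-0.99 ± 0.10, 0 of 6 higher, adjusted p = 4.03e-08). PSPC1, which encodes a paralogue of SFPQ, was higher (0.61 ± 0.13, 6 of 6, adjusted p = 0.000555), while NONO, the other paralogue, was at -0.14 ± 0.09 (1 of 6 higher, adjusted p = 0.191). KLK3, which encodes prostate-specific antigen, was at 0.08 ± 0.32 (3 of 6, adjusted p = 0.853). Without 22Rv1, KLK3 was at -0.09.

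Of 13367 genes tested, 7752 passed the threshold, 4074 higher and 3678 lower in PSF-RIP, and 8299 had an unadjusted p under 0.05. Because counts are relative, the loss of mitochondrial and structured RNA from a library raises the share of the rest; the median log2 over all genes was 0.05 after scaling.

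**Figure D2:**
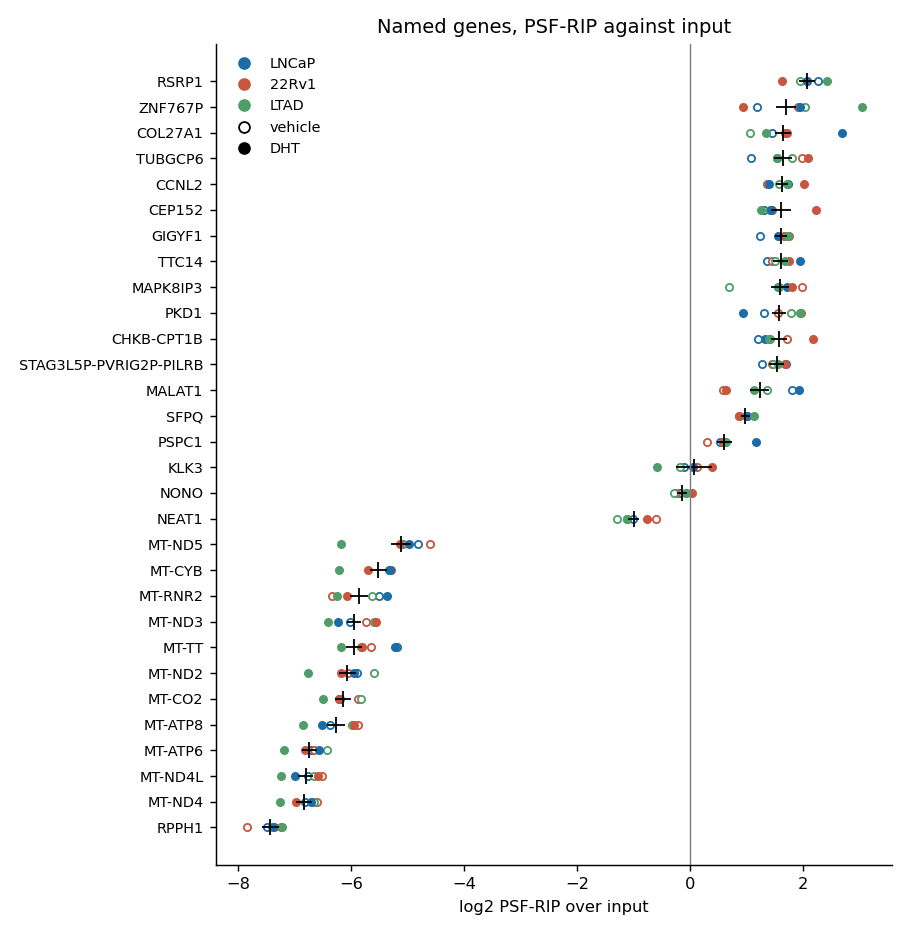
Log2 ratio of PSF-RIP over input (horizontal axis) for the named genes; each circle is 1 pair of libraries, colours are lines, open circles vehicle and filled circles DHT, and the cross with its bar is the model's estimate ± SE over the 6 pairs. RSRP1 lies at 2.08 and RPPH1 at -7.43; MALAT1 is above 0 and NEAT1 below 0 in 6 of 6 pairs.

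Groups of genes for short, abundant proteins were depleted in PSF-RIP. Of 79 ribosomal protein genes, 73 fell and 2 rose, with RPS15A at -3.87, RPS12 at -3.64 and RPS28 at -3.42, and a list median of -1.75 that was between -1.92 and -1.70 in the 6 pairs. Of 79 nuclear genes of oxidative phosphorylation, 65 fell and 8 rose (ATP5E -3.39, COX7A2 -2.56, COX6C -2.55). Of 49 replication-dependent histone genes, 44 fell and 1 rose (HIST1H4C -2.55, HIST2H2AC -1.67). Among 48 small nuclear, nucleolar and other structured RNAs, 30 fell and 7 rose (RPPH1 -7.43, RMRP -4.67, SNORA53 -3.71), and among 16 snoRNA host genes 10 fell and 4 rose (ZFAS1 -1.65, SNHG8 -1.50, SNHG3 -1.26). With the trend of counts with exonic length removed, the ribosomal protein median was -0.84 and that of oxidative phosphorylation -0.23, but the medians of histone genes (0.08), snoRNA host genes (0.24) and structured RNAs (0.38) turned positive. SNHG8 (-0.23) and HIST2H2AC (-0.06) lost their calls there. Adjusted over the list alone, the counts were 73 and 2, 65 and 8, 44 and 1, 31 and 8, and 10 and 4 in the same order of lists. In camera with the preset correlation, adjusted p-values were 8.33e-101 for ribosomal protein, 2.16e-34 for oxidative phosphorylation, 7.28e-08 for histone, 3.55e-10 for structured RNA and 0.0298 for snoRNA host genes. With an estimated correlation the adjusted p was 0.00952, 0.015, 0.667, 0.00557 and 0.667, and with line-treatment pairs as a block it was 0.11 for the ribosomal protein, oxidative phosphorylation and structured RNA lists.

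Genes for splicing factors tended to be recovered. Of 20 SR proteins and their kinases, 13 rose and 2 fell (CLK1 1.35, SRSF5 1.16, CLK2 1.08), with 13 and 3 adjusted over the list alone. Of 26 hnRNP genes, 17 rose and 3 fell both ways of adjusting (HNRNPDL 0.84, HNRNPH1 0.71, PTBP3 -1.22). Of 19 genes for paraspeckle components, 12 rose and 2 fell both ways, the latter NEAT1 and NUDT21 (-0.80), a cleavage and polyadenylation factor. The spliceosome core was split, with 37 of 79 up and 21 down (38 and 21 adjusted over the list alone), the lowest being the small proteins LSM2 (-2.30), SF3B5 (-1.72) and SNRPD2 (-1.46). In camera the SR list had an adjusted p of 0.0186, the hnRNP list 0.0236, the paraspeckle list 0.0708 (0.0404 with pairs as a block) and the spliceosome 0.412; with an estimated correlation the adjusted p was 0.667, 0.468, 0.264 and 0.943.

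Of the other lists, cell cycle genes called without the block all rose, while the rest went both ways or moved little. None of these lists, cell cycle included, passed camera with 12 libraries and no block. Among 30 cell cycle genes 16 rose and 0 fell (MCM7 1.08, MCM3 1.03, CCNB1 0.99), 15 and 0 adjusted over the list alone, with camera's adjusted p at 0.0708. Their list median was 0.594, or 0.535 with the length trend removed. With pairs as a block 19 rose and 4 fell, with an adjusted p of 0.00292 (0.332 with an estimated correlation). Of 43 androgen-induced genes 5 rose and 11 fell (SPDEF 0.58, TPD52 -0.97, KLK4 -1.0), 4 and 7 adjusted over the list alone and 14 and 15 with pairs as a block. Of 9 androgen-repressed genes 1 rose and 1 fell (0 and 1 over the list alone), the latter UGT2B15 (-0.63), whose call was lost without LNCaP (-0.37). For androgen and cholesterol synthesis 12 of 24 rose and 6 fell, 12 and 7 over the list alone (SREBF1 0.70, CYP51A1 -1.17, SRD5A3 -1.17). Of 20 p53 targets 8 rose and 6 fell (RRM2B -1.31, BTG2 -0.65, ZMAT3 -0.64), and of 23 genes of the unfolded protein response 9 rose and 4 fell (DNAJB9 -0.93, XBP1 -0.79, CANX -0.48), the same counts over each list alone. The 15 nuclear and prostate long noncoding RNAs were split 5 up and 5 down both ways (MALAT1, NEAT1, DANCR -1.27, OIP5-AS1 -1.24). Long neuronal-type genes gave 3 up and 2 down of 14 (MAGI2 1.16, with only 2 and 1 reads in LTAD input, AUTS2 0.96, NLGN1 -0.53). Luminal markers gave 6 up and 2 down of 16 (CLDN7 0.67, GATA2 0.65, CLDN4 0.38), both lists alike over the list alone. Basal markers gave 1 and 1 of 5 (DST 0.98, ITGA6 -0.53) both ways, neuroendocrine markers 1 and 3 of 8, 2 and 3 over the list alone (ENO2 0.89, DLL3 -1.42), and stromal and leukocyte markers 1 and 2 of 8, 1 and 0 over the list alone (COL1A1 1.04, HBA2 -1.01, CD68 -0.75). The call for CD68 was lost without any 1 line (-0.77 without LNCaP, -0.73 without 22Rv1, -0.75 without LTAD) and that for HBA2 without LNCaP (-0.95), and HBA2 was at 0.26 with the length trend removed. The median and the mean had opposite signs for the androgen-induced (0.02 and -0.08), long neuronal-type (-0.27 and 0.04) and neuroendocrine lists (0.09 and -0.15). With the length trend removed, the medians of the androgen-induced (-0.03), long noncoding RNA (-0.05) and neuroendocrine (-0.01) lists changed sign.

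**Figure D3:**
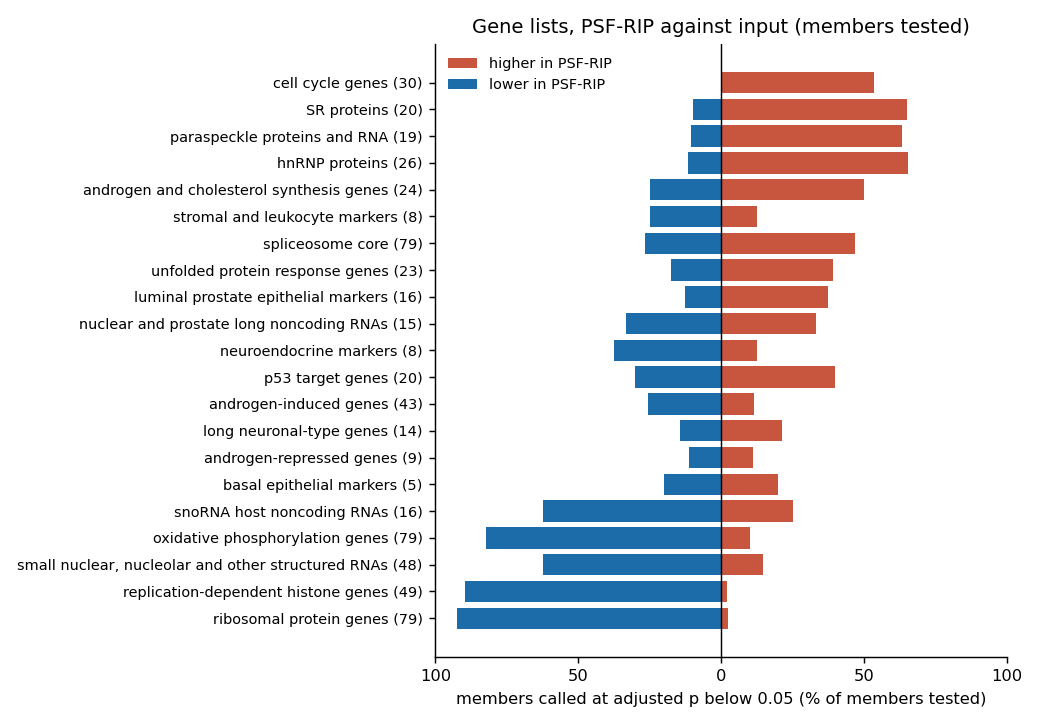
Share of the tested members of each gene list (number in brackets) called higher (right, red) or lower (left, blue) in PSF-RIP than in input at an adjusted p under 0.05, as a percent of members tested. For ribosomal protein genes 73 of 79 were lower and for hnRNP genes 17 of 26 higher; the medians of the histone, snoRNA host and structured RNA lists turned positive with the length trend removed.

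Whether enrichment with PSF differed between lines was tested as an interaction. MALAT1 was recovered less in 22Rv1 (log2 0.58 and 0.64 over input with vehicle and DHT) than in LNCaP (1.81 and 1.95), a difference of -1.27 ± 0.24 (both treatments) that did not pass over all genes (adjusted p = 0.306). With pairs as a replicate block it did (-1.27 ± 0.17, adjusted p = 2.64e-10), as it did in DESeq2 (-1.34) and without the expression filter (-1.26), and over all alternatives the adjusted p ran from 2.64e-10 to 0.424. The other differences from LNCaP were -0.15 for SFPQ, 0.02 for NONO, -0.40 for PSPC1, 0.39 for KLK3 and 0.39 for NEAT1. In LTAD the differences were -0.64 for MALAT1 (-0.63 and past the threshold in the blocked fit), 0.05 for SFPQ, -0.05 for NONO, -0.26 for PSPC1, -0.50 for KLK3 and -0.14 for NEAT1, none past the threshold without the block.

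By edgeR's quasi-likelihood test 0 of 13776 genes differed in enrichment between 22Rv1 and LNCaP (804 at an unadjusted p under 0.05) and 0 between LTAD and LNCaP (718), against 7 and 0 in DESeq2. The replicate block gave 413 genes (282 higher in 22Rv1) and 274 (135 higher in LTAD), and no expression filter gave 13 and 5. The blocked fit leaves fewer than the 4 residual degrees of freedom of the main model. Its very small p-values therefore rest largely on a spread shared over genes, not on replicates. EPS8L1 had an adjusted p of 4.96e-46 in it for 22Rv1, though the LTAD pairs lay at 5.35 (vehicle) and -5.81 (DHT). Genes of the blocked fit, chosen after their values were seen, included ATF4, a transcription factor of the integrated stress response, which was above 0 in LNCaP (0.59 with vehicle, 0.40 with DHT) and below 0 in 22Rv1 (-0.53 and -0.89), a difference of -1.20 ± 0.12 (adjusted p = 1.14e-20). ITGB1BP1 (-1.96 ± 0.27, adjusted p = 2.64e-10) was lower and RMRP (1.25 ± 0.15, adjusted p = 2.63e-12) less depleted in 22Rv1, while in LTAD GNG5 (-1.39 ± 0.18, adjusted p = 1.77e-11) was lower. Of the lists, snoRNA hosts had a lower enrichment in 22Rv1 (list median -0.81) and in LTAD (-0.47, or -0.24 with the length trend removed), with camera's adjusted p at 3.9e-08 and 0.000889; with an estimated correlation the adjusted p was 0.563 and 0.571, and 0 members passed over all genes without the block (3 and 0 adjusted over the list alone, 4 and 0 in the blocked fit). None of the other lists passed with an estimated correlation in either line, with or without the block.

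DHT changed RNA levels in the inputs of the 3 lines. FKBP5 (6:35541362-35656692), a co-chaperone gene induced by androgen, rose by log2 3.14 ± 0.23 (3 of 3 lines, adjusted p = 5.49e-05), by 2.81 in LNCaP, 2.86 in 22Rv1 and 3.81 in LTAD. SLC45A3 (1:205626981-205649630), also known as prostein, rose by 2.44 ± 0.19 (3 of 3, adjusted p = 8.6e-05). Transcripts of TTN (2:179390717-179672150), which encodes titin of muscle, were at 314 reads with DHT and 1 with vehicle over the 3 lines, a ratio of 294 (95% interval 52.3 to 11600, adjusted p = 2.87e-06). Of these reads 292 and the 1 with vehicle were from LTAD, 21 from LNCaP and 1 from 22Rv1, and without LTAD TTN was at least 7.81-fold higher. UGT2B15 (4:69512315-69536494), which encodes an androgen-conjugating enzyme, fell by 1.60 ± 0.28 (3 of 3 lines, adjusted p = 0.0204).

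Further genes that rose in 3 of 3 lines were MBOAT2 (2.52 ± 0.28), DOCK8 (2.26), DBI (2.15), GREB1 (2.14), RAB3B (2.11), SPOCK1 (1.79) and C1orf21 (1.78). In LNCaP DOCK8 went from 0 reads with vehicle to 1 with DHT and SPOCK1 from 1 to 3, so a rise there is not established. Genes that fell in 3 of 3 lines were LRRN1 (-1.48), SYTL2 (-1.42), IGFBP3 (-1.29, adjusted p = 0.0486), RNF144B (-1.14), SEMA3C (-1.13), SDC4 (-1.11), FOLH1, the gene of prostate-specific membrane antigen (-1.06), ST3GAL1 (-1.03) and TNFRSF21 (-1.0 ± 0.13). The fall of LRRN1 in 22Rv1 rested on 6 reads with vehicle and 3 with DHT. KLK3 was at 1.83 ± 0.65 and did not pass (adjusted p = 0.293). It was at 2.86 in LNCaP, 1.88 in LTAD (2 reads with vehicle, 13 with DHT) and -0.05 in 22Rv1. That difference between lines was not tested. KLK3 passed without 22Rv1 (2.86) and after thinning (2.24). SFPQ (-0.02, adjusted p = 0.973), NONO (-0.02), PSPC1 (-0.17), MALAT1 (-0.08) and NEAT1 (-0.40, adjusted p = 0.192) did not pass, though NEAT1 did in DESeq2 (-0.41). Without 22Rv1 NONO was at 0.10 and MALAT1 at 0.07, and without LTAD SFPQ was at 0.02.

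Of 43 androgen-induced genes, 8 rose over all genes and 37 rose and 1 fell adjusted over the list alone, with a list median of 1.35 (0.42 to 1.78 in the 3 lines). STEAP4, a metalloreductase gene of that list, went from 1 read with vehicle to 115 with DHT (ratio 108, 95% interval 18.9 to 4280, adjusted p = 0.00407, 2 of 3 lines). These were 87 reads in 22Rv1 and 28 in LNCaP, while LTAD went from 1 to 0; the ratio was 22.9 (3.79 to 938) without 22Rv1, and STEAP4 was at least 40.8-fold higher without LTAD. Of 9 androgen-repressed genes, 1 fell (UGT2B15) and 2 fell adjusted over the list alone. In androgen and cholesterol synthesis 3 of 24 rose, the fatty acid synthase FASN (1.07), the sterol pathway gene HMGCS1 (0.78) and IDI1 (0.69), and 12 rose and 1 fell adjusted over the list alone. Among 16 luminal markers KRT8, also an androgen-induced list member, rose (1.07) while CLDN4 (-0.60) and FOLH1 fell, with 5 up and 5 down adjusted over the list alone. For 23 genes of the unfolded protein response 0 passed over all genes and 3 rose adjusted over the list alone, and the remaining lists had 0 members called over all genes. Camera's adjusted p was 8.96e-49 for androgen-induced, 1.08e-10 for synthesis, 0.00137 for unfolded protein response, 3.14e-05 for ribosomal protein (median -0.15, or -0.08 with the length trend removed), 0.00423 for hnRNP (0.14), 0.0133 for structured RNA (-0.31, or -0.10 with that trend removed), 0.0186 for androgen-repressed and 0.0447 for cell cycle genes (0.15). With an estimated correlation the adjusted p was 0.106, 0.0551, 0.3, 0.628, 0.196, 0.148, 0.196 and 0.821. fry, which asks whether a list moves 1 way on balance, gave an adjusted p of 0.0578 for androgen-induced and 0.00635 for synthesis genes.

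In all, 85 of 13776 genes changed with DHT in input, 60 up and 25 down, and 1565 had an unadjusted p under 0.05. Other settings gave 37 (summed isoforms), 141 (DESeq2), 169 (inputs alone with the line as a block), 182 (thinned libraries), 394 (no expression filter) and 0 genes (no term for the line). Without 22Rv1 24 genes passed, 12 of them among the 85, and without LTAD 54 passed, 42 of them among the 85. Without 22Rv1 the call remained for FKBP5, SLC45A3, TTN, DBI, RAB3B and TNFRSF21 and was lost for the other genes called above, all with the same sign and SPOCK1 at 2.55. Without LTAD it was lost for TTN, LRRN1, SYTL2, RNF144B, FOLH1, HMGCS1, FASN, IDI1, KRT8 and CLDN4, and without LNCaP for UGT2B15, IGFBP3, IDI1 and CLDN4.

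**Figure D4:**
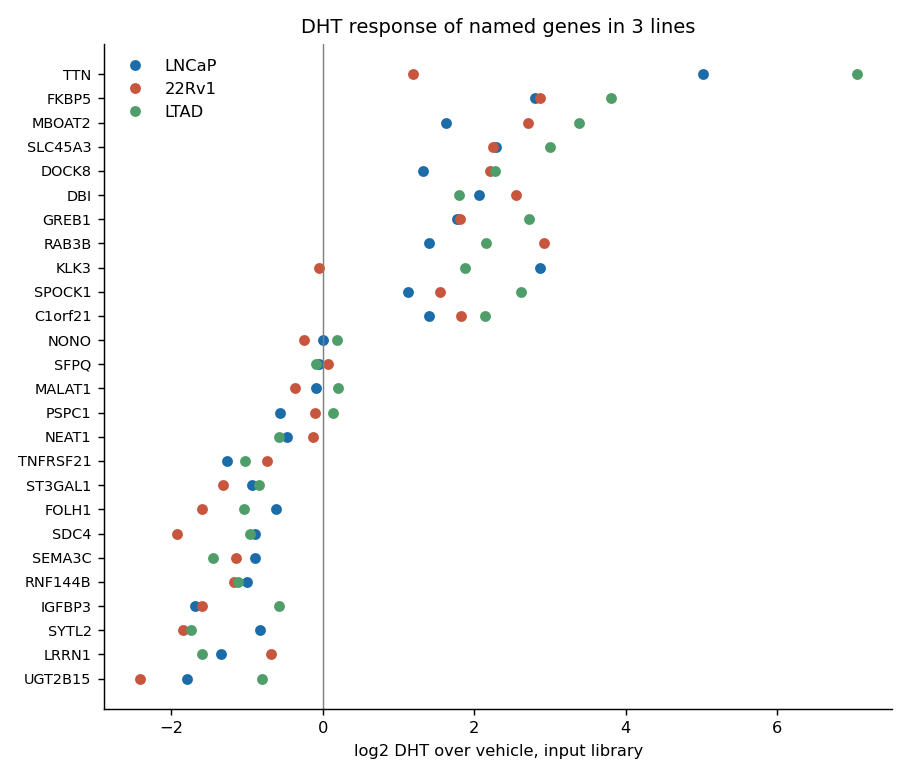
Log2 ratio of DHT over vehicle in the input libraries (horizontal axis) of the named genes, 1 point per line from 1 library each. FKBP5 lies at 2.81 or above in each line and KLK3 at 2.86 in LNCaP but -0.05 in 22Rv1.

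DHT was also tested for an effect on enrichment with PSF beyond that on the input. The differences were 0.04 for SFPQ, 0.21 for NONO, 0.33 for PSPC1, -0.11 for KLK3, -0.03 for NEAT1 and -0.01 for MALAT1, none past the threshold; leaving out LNCaP put KLK3 at 0.36 and NEAT1 at 0.01, leaving out 22Rv1 put NEAT1 at 0.03, and leaving out LTAD put SFPQ at -0.01 and MALAT1 at 0.10. By edgeR's quasi-likelihood test 0 of 13776 genes passed (225 at an unadjusted p under 0.05), against 0 in DESeq2 and 7 with pairs as a replicate block (3 higher, 4 lower with DHT). Among those 7, chosen after their values were seen, UQCRB of respiratory complex III was at 0.66 ± 0.13 (adjusted p = 0.00367), MT-ND5 at -0.59 and MT-ND6 at -0.91 ± 0.11 (adjusted p = 3.2e-13). For MT-ND6 the LTAD pairs went from -0.18 with vehicle to -2.55 with DHT, while LNCaP (-2.59 and -2.75) and 22Rv1 (-1.78 and -2.04) moved less. The caution given above for p-values of the blocked fit holds here too. Without the block no gene list had a member called over all genes, and with it 1 oxidative phosphorylation gene (UQCRB) and 1 ribosomal protein gene rose. Camera's adjusted p in the blocked fit was 4.23e-07 for histone and 0.00271 for ribosomal protein genes, and 0.644 for both with an estimated correlation.

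Levels in input differed widely between 22Rv1 and LNCaP. Genes read in 22Rv1 and not at all in LNCaP input included HSPB6, a small heat shock protein gene, at least 440-fold higher, RGS2, a regulator of G protein signalling (at least 382-fold), HIST1H4D (309-fold), GPM6A (218-fold), FAM110B (215-fold), HGF, the hepatocyte growth factor gene (191-fold), the synaptic vesicle gene SV2A (184-fold), the neural splicing factor gene SRRM4 (177-fold) and the glutamate receptor gene GRIN3A (163-fold), all lower bounds. Genes read in LNCaP input and not at all in 22Rv1 input were the chemokine receptor gene ACKR3 (at least 221-fold lower in 22Rv1), the deiodinase gene DIO3 (133-fold), MAGEA10 (114-fold), RAB25 (109-fold), PXDN (103-fold), PTPRM (64.2-fold), PCDHB5 (61.6-fold), NLRP2 (61.2-fold), NXN (60-fold) and PARP10 (52.8-fold). These bounds concern the inputs of the 2 lines alone: HGF had 43 reads in the LNCaP vehicle PSF-RIP library and 1866 in that of 22Rv1, PARP10 had 9 in the 22Rv1 vehicle PSF-RIP library, and ACKR3 had 190 and 115 reads in LTAD input. NEAT1 (-3.35 ± 0.16, adjusted p = 3.4e-08), KLK3 (-3.34 ± 0.68, adjusted p = 0.00159; -1.74 with vehicle and -4.65 with DHT) and NONO (-0.84 ± 0.15, adjusted p = 0.000793) were lower in 22Rv1 with both treatments. MALAT1 was at -0.44 (adjusted p = 0.0483), a call lost with median-ratio scaling. PSPC1 was higher (0.78, adjusted p = 0.0231), a call lost in DESeq2 and after thinning. SFPQ (-0.25, adjusted p = 0.133) did not pass.

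Histone, cell cycle and unfolded protein response genes were higher in 22Rv1. Of 50 histone genes 45 rose and 1 fell, of 30 cell cycle genes 25 rose and 1 fell (CCNA2 4.03, CDC20 2.95, MCM7 1.59) and of 23 genes of the unfolded protein response 17 rose and 0 fell (CRELD2 3.76, MANF 3.32, PDIA4 2.52), with the same counts adjusted over the list alone. Of 9 neuroendocrine markers 6 rose and 1 fell both ways, among them SYP (4.10) and SCG3 (at least 83.2-fold). In androgen and cholesterol synthesis 14 of 24 rose and 4 fell, 15 and 4 over the list alone (CYP51A1 1.72, INSIG1 1.69). Of 20 p53 targets 2 rose and 10 fell both ways (SESN1 -2.07, BTG2 -1.85, TP53INP1 -1.47), and of 80 ribosomal protein genes 6 rose and 31 fell both ways. Camera's adjusted p was 9.64e-12 for histone, 7.45e-06 for cell cycle, 5.85e-09 for unfolded protein response, 0.0102 for neuroendocrine, synthesis and ribosomal protein, and 0.0418 for p53 genes. With an estimated correlation the adjusted p was 0.485, 0.597, 0.432, 0.485 for neuroendocrine and synthesis, 0.746 for ribosomal protein and 0.541 for p53 genes. The androgen-induced list was split with 15 of 43 up and 10 down (16 and 11 over the list alone). Its median changed sign with treatment, at 0.642 with vehicle and -0.255 with DHT. Luminal markers gave 3 up and 6 down of 16 both ways, with KRT19 higher (255 reads against 1, ratio 203, 95% interval 36.1 to 8040) and GATA2 lower (-1.65), and stromal and leukocyte markers 4 up and 4 down of 10 both ways (ALB at least 72.3-fold higher, FN1 -5.21). In all 6874 of 13776 genes differed, 3658 higher and 3216 lower in 22Rv1. The vehicle and DHT libraries served as the 2 samples of each line, so these p-values do not measure variation between cultures of a line.

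Between LTAD and LNCaP fewer genes passed. TRIB2, which encodes a pseudokinase, was at log2 5.73 ± 0.34 in LTAD (both treatments, adjusted p = 8.32e-06) and PEG10, an imprinted retrotransposon-derived gene, had 164 reads against 2 (ratio 95.4, 95% interval 26 to 794). The metalloproteinase gene MMP16 was at least 192-fold lower, the clusterin gene CLU at least 108-fold lower, and ADAMTS1 at -7.54 ± 0.25 (adjusted p = 9.93e-09). KLK3 was at -6.14 ± 0.91 (adjusted p = 0.00187). NEAT1 (-1.82 ± 0.15, adjusted p = 2.21e-05) and MALAT1 (-1.45 ± 0.17, adjusted p = 0.000382) were lower in LTAD, while SFPQ (-0.44, adjusted p = 0.0752), NONO (-0.18) and PSPC1 (0.16) did not pass. The other genes at the top were TMTC1 (4.93), SPOCK1 (4.71), the receptor gene FGFR2 (3.91), TTN (3.76, a call lost in DESeq2; 292 reads against 21 with DHT but 1 against 0 with vehicle), SSFA2 (3.61), PNMA2 (3.49), GPC6 (24 reads against 2, ratio 14, 95% interval 3.47 to 122) and FRAS1 (16 reads against 0, at least 6.21-fold, or 4.49-fold at the lower end of the exact 95% interval). The others at the bottom were ASPH (-5.95), GALNT7 (1 read against 171, 147-fold lower, 95% interval 26 to 5840), TOX3 (1 against 53, 45.6-fold lower, 7.83 to 1830), AQP3 (1 against 41, 35.2-fold lower, 5.98 to 1430), MAGEA4 (at least 6.59-fold lower) and UGT8 (at least 2.86-fold lower, a call lost in DESeq2 and after thinning). The bounds concern input alone: CLU had 44 reads in the LTAD DHT PSF-RIP library and FRAS1 24 in the LNCaP vehicle PSF-RIP library.

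Of 23 genes of the unfolded protein response 7 rose and 1 fell in LTAD (TRIB3 0.86, PDIA4 0.71, HYOU1 -0.63), 9 and 2 adjusted over the list alone, and of 16 luminal markers 0 rose and 5 fell (FOLH1 -2.29, CLDN4 -1.25, CDH1 -1.0), 2 and 6 over the list alone. For androgen and cholesterol synthesis 1 of 24 rose and 5 fell (SREBF1 -1.12, FASN -1.08), 5 and 6 over the list alone, and of 43 androgen-induced genes 3 rose and 6 fell both ways (TPD52 1.05, ACPP -2.57). Of 9 neuroendocrine markers 2 rose (ENO2 0.97, and NTS with 62 reads against 2, ratio 36.1, 95% interval 9.57 to 304). Of 30 cell cycle genes 0 were called by edgeR over all genes or over the list alone, with a list median of 1.08. That median was 2.13 with vehicle and 0.18 with DHT, that of histone genes 2.27 and -0.02 and that of oxidative phosphorylation genes 0.39 and 0.06, so these shifts lay mostly in the vehicle libraries, 1 per line. Camera's adjusted p was 0.000339 for cell cycle and oxidative phosphorylation (list median 0.24), 0.000406 for histone (0.94), 0.0148 for unfolded protein response and 0.0248 for structured RNA genes (-0.44). With an estimated correlation the adjusted p was 0.717 for cell cycle and histone, 0.556 for oxidative phosphorylation, 0.532 for unfolded protein response and 0.483 for structured RNA genes. In all 1131 of 13776 genes differed, 403 higher and 728 lower in LTAD. Here too the vehicle and DHT libraries served as the samples of each line.

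CLIP-seq, in which RNA is crosslinked to protein by ultraviolet light before precipitation, gave peak lists of unequal size in LNCaP. They held 24242 (vehicle list 1), 23580 (DHT list 1), 7691 (vehicle list 2) and 13546 peaks (DHT list 2), with median widths of 491, 410, 139 and 158 bp. Introns held 68.5%, 67.1%, 46.5% and 65.5% of the peaks in that order, against 56.4% to 56.5% of peaks placed at random. Between genes lay 15.6%, 16.6%, 50.6% and 27.3%, against 38.1% at random. Coding exons held 5.25%, 5.44%, 0.22% and 0.77%, against 1.24% to 1.33% at random. The first list of each treatment thus lay above random for coding exons and the second below. UTRs held 5.8%, 6.37%, 0.94% and 2.72%, against 1.77% to 1.79% at random. Within the first list of each treatment the density rose with the reads of a gene in LNCaP, from 1.74 (vehicle) and 1.71 (DHT) peaks per Mb in genes with 0 reads to 60.7 and 66.8 in the 41 genes with 10000 reads or more. In the second lists it went from 1.27 to 15.7 (vehicle) and from 2.1 to 40.5 (DHT).

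**Figure D5:**
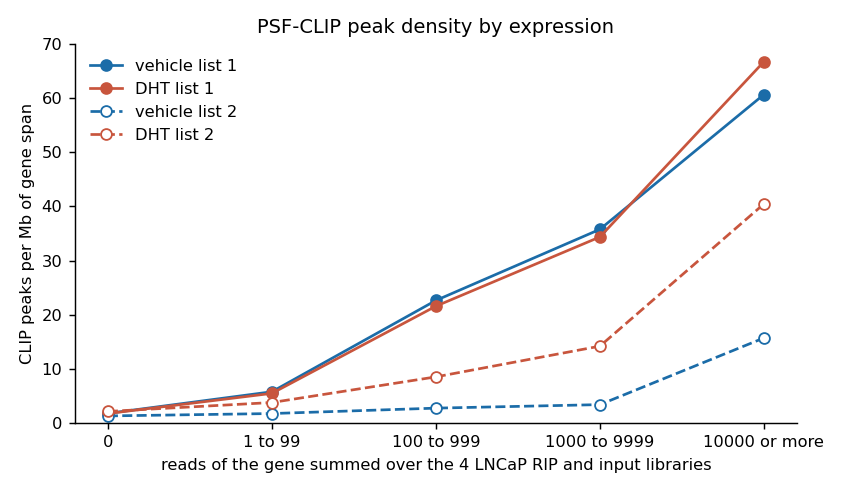
PSF-CLIP peaks per Mb of gene span (vertical axis) in LNCaP for genes grouped by their summed reads in the 4 LNCaP libraries (horizontal axis); blue vehicle, red DHT, solid lines list 1, dashed lines list 2. The top group holds 41 genes and reaches 66.8 peaks per Mb in DHT list 1 and 15.7 in vehicle list 2.

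The overlap of the lists depended on the pair and on the measure. Of vehicle list 1, 58.0% of peaks touched a peak of DHT list 1 and 6.9% a peak of vehicle list 2, against 1.17% and 0.16% for peaks shuffled within genes. Of DHT list 1, 62.3% touched vehicle list 1 and 21.9% touched DHT list 2. Of vehicle list 2, 24.8% touched vehicle list 1 and 16.6% DHT list 2, and of DHT list 2, 42.7% touched DHT list 1 and 9.13% vehicle list 2. Relative to the shuffles the order of pairs differed: DHT list 1 was at 50.1 times the shuffled share with vehicle list 1 and at 57.2 times with DHT list 2, and vehicle list 2 at 27.3 times with vehicle list 1 and at 78.9 times with DHT list 2. The lists differ in size and peak width, so no order of overlap is drawn from these shares. With 2 lists per treatment no test of DHT was made.

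Both lists shared 1672 peaks of vehicle list 1 and 5156 of DHT list 1. Scores at the top were tied at 3100, reached by 18 of the shared vehicle peaks and 13 of the shared DHT peaks, and ties were ordered by position. A peak is named by the gene it touches and classed by its midpoint over all annotated genes, so name and class can come from different genes. Of the 200 highest shared vehicle peaks, 58 had at least 50% of their 12-base words repeated, against at most 3 in random placements. The highest shared vehicle peaks classed as intronic touched ATP9B (18:77068352-77069799, score 3115.54), IDI1 (10:1092349-1093857), FAM87B (1:755196-759135), ATP10A (15:26002874-26004241), RPH3AL (17:164209-167429), ABR (17:1020288-1022835) and SLC27A5 (19:59013309-59014776). The others were classed as exonic at TP73-AS1 (1:3655732-3656967), as UTR at SEC14L1 (17:75211503-75212621) and as between genes at 10:133730019-133734003. The highest shared DHT peak was classed as intronic and touched PHF2 (9:96433208-96435357, score 3230.05). It was followed by peaks at FAM87B, TP73-AS1, ATP10A, RPH3AL, ABR, SLC27A5, SNTG2 (2:1101628-1104839), MIR99AHG (21:17766378-17771104) and AFDN (6:168340671-168342578). PSPC1 carried 9, 3, 1 and 4 peaks (vehicle 1, DHT 1, vehicle 2, DHT 2), SFPQ 2, 3, 2 and 4, NEAT1 1, 0, 3 and 7, and MALAT1 0, 0, 1 and 1, while KLK3 and NONO carried 0 in each list. The most peaks in vehicle list 1 were in the long genes NAALADL2 (70), LRBA (61), NCAM2 (59), IMMP2L (52) and NLGN1 (48).

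Genes with at least 1 CLIP peak in each list of a treatment were compared with those recovered in PSF-RIP. The peaks of the lists did not have to overlap. Of genes with such peaks 36.4% were higher in PSF-RIP, against 28.7% of the rest, an odds ratio of 1.42 (95% interval 1.31 to 1.55, Fisher's exact test p = 6.66e-16, 13341 genes tested outside the mitochondrial genome). Over deciles of gene span the Mantel-Haenszel odds ratio was 1.21 (1.1 to 1.32, p = 9.78e-05, n = 13341 genes) and over deciles of expression 1.05 (0.96 to 1.15, p = 0.294). Expression was the summed reads of the 4 LNCaP libraries, input and PSF-RIP. It shares reads with the PSF-RIP call, so the value over expression does not show that abundance accounts for the association. Genes are not independent replicates. The odds ratio was 1.12 (p = 0.329, n = 13341 genes) with a log2 above 1 in both LNCaP pairs in place of the call over lines (1.43 over span, p = 0.00485), 1.08 (p = 0.104) over span with a peak in any list, and 1.19 (p = 0.0251) over expression with a peak in all 4 lists.

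The log2 of PSF-RIP over input rose with gene span across 13749 genes, with Spearman's rho at 0.078 and 0.082 in LNCaP (vehicle and DHT), 0.142 and 0.128 in 22Rv1, and 0.221 and 0.162 in LTAD. The sign was positive in 6 of 6 pairs. No p is given, since genes are not independent replicates. With exonic length in place of span rho ran from 0.171 in LNCaP vehicle to 0.33 in LTAD vehicle.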

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

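The test of histone genes by exonic length was chosen only after the result was seen. Among 30 genes of the PSF-RIP comparison, 1 pair stood far from the other 5 in 3 genes, where chance gives about 1 in 20. CEP152 was at a log2 of 2.24 over input in 22Rv1 with DHT (1.27 to 1.47 in the other pairs), MAPK8IP3 at 0.69 in LTAD with vehicle (1.57 to 1.98) and MT-ND5 at -6.18 in LTAD with DHT (-5.13 to -4.61). The cause was not tested.

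Reads outside sense exons, which the tests of genes in the report did not use, also differed between PSF-RIP and input for single genes. Intron reads were higher in PSF-RIP for 1231 of 11392 genes and lower for 1008, with SRSF5 at 1.79, MAT2A at 1.78 and SRSF6 at 1.75. MIR663AHG (2.18) and HMGB1 (1.95) rose more, while HMCN2 (-6.89) and KCTD19 (-6.02) fell further than any of these rose. Antisense reads were higher for 523 of 2669 genes and lower for 441, with ANKDD1A at 1.95 and SLC9A3 at 1.80. CES5AP1 (2.50) rose more, while LHFPL3-AS2 (-6.59) and PCBD2 (-6.12) fell.

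The first pattern weighed was the loss of short mRNAs, those of ribosomal proteins and histones, from PSF-RIP. Ribosomal protein genes stayed at -1.305 (95% interval -1.663 to -0.929, 63 of 79 genes) below genes matched on exonic length and expression. That argues against length as the whole cause. Their median was -1.94 with every library thinned and -1.752 without mitochondrial genes, RPPH1 and RMRP. Thinning keeps the expected scaled fold of a gene, and TMM scaling already trims extreme genes. Both medians could therefore hardly move and cannot decide on depth or a few abundant genes. MALAT1, abundant in PSF-RIP, was not left out. The histone median was 0.079 with the length trend removed, so a length bias may account for that part. The lower binding of these mRNAs by PSF stays open as a hypothesis, since no immunoglobulin control library was analysed here. Of 100 splits of the 12 libraries, 1, the real one, gave as many genes as the 7752 of the PSF-RIP comparison. The highest other gave 3232, from a split that parted 4 of the 6 pairs. Splits that do not part all 6 pairs put the difference between assays into the error, so they are unlike the real one. The 9 others drawn that part all 6 pairs gave at most 2, and 9 are too few to exclude chance.

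The second pattern was that genes differed in enrichment with PSF at all. The intron to exon read ratio in the input of 1 line correlated with enrichment in the other 2 lines, with exonic length and expression held fixed (partial Spearman 0.199 in the lowest case, 0.313 and 0.219 in the others), so a higher recovery of unspliced transcripts may contribute. For the 85 genes that changed with DHT in input, 1 of the 10 splits of the 6 line-treatment pairs gave as many (highest other 1). For that count 10 splits are too few for a share under 0.05. Enrichment changed with DHT for 0 genes in edgeR (225 at an unadjusted p under 0.05) and 0 in DESeq2. All 10 splits gave as many (highest other 1), but any split gives at least 0, so they cannot decide there.

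The third pattern was the CLIP lists. The smaller number of peaks of vehicle list 2 does not account for its 50.6% between genes, since the same number of top peaks put at most 29.22% there in the other lists. Without the 57 intervals of 1 Mb holding 10 or more of its peaks, which held 1948 of 7690 peaks, the share was 37.18%, between the bounds set for that test, so piled-up peaks and another cause cannot be told apart. In the 200 highest shared vehicle peaks a median of 1.28% of 12-base words occurred more than once, against a mean of 0.49% and a highest of 0.75% in random placements. By the bounds set for that test the median leaves tandem repeats open as an explanation of these peaks as a set. In 58 of these peaks at least 50% of the words were repeated, against at most 3 at random, so that part was rich in repeated sequence. No biological explanation was tested for the CLIP lists.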

How the results depend on the processing

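Leaving out mitochondrial genes, RPPH1 and RMRP, thinning, removing the length trend, and the block with the length trend removed were chosen only after the data were seen; the cause of the changes below was not tested unless stated. The count for PSF-RIP vs input ran from 6045 (thinned) to 8497 (blocked), that for 22Rv1 against LNCaP input was 4947 or higher and that for LTAD against LNCaP input ran from 868 to 1663. Of 3856 values of single genes under alternatives, 3624 kept direction and side of the threshold, 134 lost the call, 61 gained it and 37 changed sign. Without the expression filter 13 genes differed in enrichment between 22Rv1 and LNCaP, 5 between LTAD and LNCaP, and 394 changed with DHT in input. DESeq2 gave 7 for enrichment in 22Rv1 and 141 for DHT in input, with KLK3 (PSF-RIP vs input) at -0.054, NONO at -0.049 for enrichment in 22Rv1, and KLK3 at 0.054 and MALAT1 at 0.005 for DHT in enrichment. Summed isoforms gave 37 genes for DHT in input, SFPQ at 0.002 there, and KLK3 at 0.134 and MALAT1 at 0.003 for DHT in enrichment. Median-ratio scaling put NONO at -0.049 for enrichment in 22Rv1 and MALAT1 at 0.005 for DHT in enrichment. Without mitochondrial genes, RPPH1 and RMRP, NONO was at 0.005 for enrichment in LTAD and MALAT1 at 0.015 for DHT in enrichment. Thinned libraries gave 182 genes for DHT in input, SFPQ at -0.244 and KLK3 at 0.242 for enrichment in LTAD, SFPQ at 0.015 and PSPC1 at 0.082 for DHT in input, and NEAT1 at 0.094 and MALAT1 at 0.004 for DHT in enrichment. With the length trend removed HBA2 was at 0.255 in PSF-RIP against input (0.215 with the block), NONO at -0.059 for enrichment in 22Rv1, SFPQ at 0.002 for DHT in input, and NEAT1 at 0.07 and MALAT1 at 0.062 for DHT in enrichment. The pairs as a replicate block gave 413 genes for enrichment in 22Rv1, 274 for enrichment in LTAD and 7 for DHT in enrichment, with KLK3 at 0.173 there. The 8 libraries of LNCaP and 22Rv1 alone gave 1 gene for enrichment. Inputs alone with the line as a block gave 169 genes for DHT. With no term for the line, DHT in input gave 0 genes in edgeR and NONO at 0.01; by construction the differences between lines then enter the error. Vehicle libraries alone put KLK3 at -0.01 in PSF-RIP against input. Leaving out 1 line at a time gave 24 to 120 genes for DHT in input, with SFPQ from -0.058 to 0.021, NONO from -0.11 to 0.1, HIST1H2AC from -0.588 to 0.08 there, MALAT1 (DHT vs vehicle in input) from -0.218 to 0.067 and CD68 (DHT vs vehicle in input) from -1.623 to 0.366; KLK3 from -0.091 to 0.116 in PSF-RIP against input; and SFPQ from -0.005 to 0.071, KLK3 from -0.09 to 0.363, NEAT1 from -0.128 to 0.031 and MALAT1 from -0.085 to 0.097 for DHT in enrichment. A reciprocal overlap of 50% put the shared CLIP peaks at 49.06% (vehicle 1 in DHT 1), 0.65% (vehicle 1 in vehicle 2), 50.44% (DHT 1 in vehicle 1), 6.01% (DHT 1 in DHT 2), 2.05% (vehicle 2 in vehicle 1), 11.55% (vehicle 2 in DHT 2), 10.45% (DHT 2 in DHT 1) and 6.56% (DHT 2 in vehicle 2). Equal numbers of top peaks gave 62.34%, 16.94%, 64.58%, 32.56%, 19.82%, 13.75%, 36.62% and 13.13% in that order, and the upper 50% by score 60.19%, 5.91%, 64.22%, 21.27%, 15.47% and 8.37%, the pairs of DHT lists aside. For CLIP against PSF-RIP, a log2 above 1 in both LNCaP pairs gave an odds ratio of 1.121, a peak in any list 1.075 over span, and a peak in all 4 lists 1.187 over expression. Exonic length in place of span put rho at 0.171, 0.273 and 0.33 with vehicle and 0.189, 0.235 and 0.26 with DHT (LNCaP, 22Rv1, LTAD), and the upper 50% of expression at 0.14, 0.202 and 0.302 with vehicle and at 0.148 (LNCaP) and 0.222 (LTAD) with DHT. A pseudocount, the second LNCaP set and its upper 50% were not run, since the values are counts and that set could not be matched to samples. At the depth of the shallowest library fewer genes passed for PSF-RIP vs input (6045 against 7752) and more for DHT in input (182 against 85), so depth was not shown to limit the DHT calls.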

Other observations

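The long noncoding RNAs MALAT1 and NEAT1, both of the nucleus, went opposite ways in PSF-RIP. MALAT1 was at 83927.6 (vehicle) and 86671.4 (DHT) TMM-scaled CPM (reads over library size times its scaling factor) in the LNCaP PSF-RIP libraries against 23914.8 and 22488.6 in the inputs. In 22Rv1 it was at 29034.3 and 23455.2 against 19368.6 and 15017.3, and in LTAD 20298.4 and 19863.8 against 7869.8 and 9068.34. NEAT1 was at 3810.62 and 2746.61 CPM in LNCaP input, 331.36 and 301.66 in 22Rv1 and 1121.02 and 749.47 in LTAD.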
